A study of Mus musculus with 9 samples.

How the data were processed

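Gene signals were measured in the brain of male mice on Clariom S mouse arrays, with 3 arrays in each of 3 groups: wild type given vehicle, ob/ob given vehicle, and ob/ob given VE at 100 mg/kg for 42 days. The deposited values were log2 signals, made by the authors with signal space transformation and robust multi-array averaging in Transcriptome Analysis Console 4.0.2, per the labels' protocols. Per the same protocols, 100 ng of RNA was used and arrays were hybridized for 16 h at 45 C. The description of the second VE array named its unit as log2 in other words than those of the other 8, and its values were on the same scale. Of the 22206 probe sets, 19572 carried 1 gene symbol and 2634 carried none, and they covered 19505 genes, of which 55 had more than 1 probe set. Symbols came from the deposited platform annotation, and a RefSeq table on GRCm38.p6 was used for chromosomes and neighbourhoods alone.

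Differences between groups were computed with limma 3.58.1 in R 4.3.3 on the deposited log2 values without a further normalization. A mean per group was fitted over the 9 arrays, with empirical Bayes moderation (6 residual and 7.03 prior degrees of freedom) and Benjamini-Hochberg adjustment over the 22206 probe sets, and probe sets at adjusted p under 0.05 were called. Sequencing depth does not apply to arrays. The precision was set by 3 arrays per group: the smallest called changes were 0.85, 1.01 and 1.14 log2 units in the 3 comparisons, and the called genes named in the report had an SE of 0.191 to 0.454. The comparisons were ob/ob vehicle against wild type, VE against ob/ob vehicle, VE against wild type, and any difference among the 3 groups by the moderated F test. The authors' rule, per the design text, was unadjusted p under 0.05 with a fold over 1.1, and it was run as an alternative. Detection calls (0.05) and the area-under-curve filter (0.7) of the design text were not used here.

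Gene lists were written before the data were examined, by symbols for brain regions, cell types, pathways and label checks and by 3 symbol patterns for olfactory receptors, vomeronasal receptors and keratin-associated genes. Lists with at least 4 measured members, 56 in number, were tested with camera of limma with a preset inter-gene correlation of 0.01, and adjusted over the lists of a comparison. Camera with an estimated correlation and fry were the alternatives. A list's median is the median log2 change of its members, and its SE over arrays comes from the per-array list medians (n = 3 per group). Counts "adjusted over the list alone" used the p values of the members only. The label-check lists for sex and strain had 3 measured members each and were not tested.

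Genes were named by a rule fixed before the data were examined. Only probe sets with 1 symbol were used, and the probe set with the highest mean stood for a gene. For the first 2 comparisons these were the 12 largest rises and 12 largest falls among called genes, filled to 12 with the smallest unadjusted p among probe sets above the median level, and for VE against wild type 5 each way. To these came up to 4 members of each list with the smallest p, and the key genes Lep, Lepr, Agrp, Npy, Pomc, Cartpt, Socs3, Bdnf, Ttr, Gfap, Fkbp5 and Nnt with the label checks Xist and Ddx3y. Predicted genes and chemosensory receptors were counted but skipped in the fill. Pik3ip1 in ob/ob against wild type was chosen after its values were seen.

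The reversal of the ob/ob change by VE was measured as the covariance over probe sets of the 2 changes, set beside the covariance that the shared ob/ob arrays give without an effect, and tested by exact permutation over 1680 assignments of the 9 arrays. That permutation exchanged arrays among all 3 groups. Its null is that the 3 groups are alike, not the lack of a VE effect alone. Separation of the groups was measured by a pseudo-F on Euclidean distances with exact permutation over 280 assignments. Level-matched random lists were drawn 10000 times in 20 bins of mean signal.

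Alternatives fixed before the data were examined were the authors' rule, adjusted p under 0.1, trend and robust moderation, probe sets above the median level, quantile normalization, centring of arrays, array weights, probe sets with 1 symbol, the replicate number as a block, the 2 compared groups alone, and leaving out each array. Cyclic loess, scaling of arrays to equal SD, quantile normalization without VE array 2, and 1 probe set per distinct set of values were added after the data were seen. The scripts were tested on simulated data with 200 of 22206 probe sets changed. For ob/ob against wild type limma recovered 0%, 42% and 99.5% of changes of 0.5, 1 and 2 log2 units, for VE against ob/ob 0%, 41% and 100%, and for VE against wild type 0%, 32.5% and 99.5%. At those sizes limma made 2, 8 and 11 false calls for ob/ob against wild type. It made 0, 11 and 9 for VE against ob/ob, and 0, 4 and 8 for VE against wild type. Camera recovered a moved list (adjusted p 4.34e-13) and called 0 of 50 unmoved lists. Those lists were simulated, so the result does not show how camera behaves on real lists, whose members can be correlated.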

Results

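In the brain of leptin-deficient ob/ob mice given vehicle, 2 of 15 choroid plexus, 2 of 13 myelin, 3 of 13 astrocyte and 2 of 8 thalamus genes were called, and these were lower than in wild-type mice. The 4 lists were lower by camera with a preset correlation (medians -0.84, -0.99, -0.68 and -0.53), and adjusted p = 0.374 to 0.403 with an estimated correlation, at which 0 of 56 lists passed by camera (6 at unadjusted p under 0.05). Tcf7l2, a transcription factor of thalamic neurons, fell by 2.33 log2 units (SE 0.308, limma adjusted p 0.0118, n = 3 per group). Fa2h, an enzyme of myelin lipids, fell by 1.66 (SE 0.216, limma adjusted p 0.0118, n = 3). The calls of Tcf7l2 and Fa2h ended without ob/ob array 2 or 3 or wild-type array 2 or 3 (limma adjusted p up to 0.118 over the alternatives). The olfactory receptor list was higher in ob/ob brain by camera with a preset correlation, with a median of 0.36, and adjusted p = 0.113 with an estimated correlation. Taken from the per-array list medians, its difference was 0.349 (SE over arrays 0.0698, n = 3), and 0.197 (SE 0.0446) after quantile normalization. In ob/ob mice given a Vigna umbellata extract (VE), Pik3ip1, an inhibitor of phosphoinositide 3-kinase, rose by 1.48 against ob/ob vehicle (SE 0.268, limma adjusted p 0.0366, n = 3). The orphan nuclear receptor gene Nr4a2 fell by 1.82 (SE 0.267, limma adjusted p 0.0334, n = 3). Both calls ended with 1-symbol probe sets alone, with the 2 compared groups alone and without any single ob/ob array (limma adjusted p up to 0.212 and 0.209 over the alternatives). The sialyltransferase gene St6galnac5 was lower in VE than in wild-type brain by 2.04 (SE 0.233, limma adjusted p 0.0174, n = 3). After quantile normalization that call was lost (change -1.56, limma adjusted p 0.167, range 1.6e-06 to 0.244 over the alternatives).

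The deposited values were log2 signals of 22206 probe sets on 9 Clariom S mouse arrays, with 3 male mice per group by the labels. The groups were wild type given vehicle, ob/ob given vehicle, and ob/ob given VE at 100 mg/kg by gavage for 42 days. The replicates are separate animals only as far as the labels say. The design text also named white adipose tissue and a dose of 50 mg/kg, while the labels named brain and 100 mg/kg, and the lower dose was not analysed here. The second VE array stood apart: its correlation with the other 8 arrays was 0.962 to 0.970, against 0.979 to 0.993 among those 8, its SD over probe sets was 2.38 against 2.56 to 2.84, and its median was 7.01 against 7.12 to 7.23. Arrays are named below by group and by the replicate number of the labels.

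Choroid plexus genes were among the largest named falls in ob/ob brain against wild type. Folr1, the folate receptor of the choroid plexus, fell by 2.06 (SE 0.324), from 9.36 (SD 0.802) to 7.30 (SD 0.271), with a limma adjusted p of 0.0236 (0.000403 to 0.148 over the alternatives, n = 3). Kl, the gene of the ageing-related hormone klotho, fell by 2.01 (SE 0.422, limma adjusted p 0.0434, range 0.00115 to 0.203). Ace, which makes angiotensin II, fell by 1.96 (SE 0.424, limma adjusted p 0.0463, range 0.0015 to 0.205). Ecrg4, a secreted peptide precursor of choroid plexus epithelium, fell by 2.34 (SE 0.395, limma adjusted p 0.0284, range 0.000403 to 0.182). The growth factor gene Igf2 fell by 1.92 (SE 0.281), from 12.80 (SD 0.194) to 10.89 (SD 0.581), with a limma adjusted p of 0.0193 (range 0.000275 to 0.143). Cfap126, a gene of motile cilia, fell by 1.91 (SE 0.319, limma adjusted p 0.0284, range 0.000533 to 0.177). Pltp, a phospholipid transfer protein, fell by 1.64 (SE 0.291, limma adjusted p 0.0326, range 0.000885 to 0.186). The choroid plexus list of 15 genes fell with a median of -0.84 (camera adjusted p 3.93e-06, and adjusted p = 0.394 with an estimated correlation), with 2 members called over all genes and 4 when adjusted over the list alone. At most 2 of the called genes named above therefore belonged to that list, and the rest were named for the size of their fall. Its medians in the 3 ob/ob arrays, taken from the wild-type mean, were -0.41, -1.17 and -0.72, and in the 3 wild-type arrays -0.35, 0.25 and 0.14, so that wild-type array 1 stood next to ob/ob array 1. Ttr, the thyroid hormone carrier made by the choroid plexus, was lower by 2.08 (SE 0.985, SD 2.19 in ob/ob) and did not pass (limma adjusted p 0.259, range 0.0234 to 0.696). Ttr stood at 15.10 on ob/ob array 2 against 19.31 and 18.24 on the other ob/ob arrays, and its change was -0.86 without that array (-2.96 to -0.86 over the alternatives).

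Called genes of the myelin and astrocyte lists were lower in ob/ob brain. Fa2h went from 9.25 (SD 0.331) to 7.59 (SD 0.111), n = 3, with a limma adjusted p of 0.000147 to 0.118 and a change of -1.85 to -1.55 over the alternatives. Cryab, a small heat shock protein of oligodendrocytes, fell by 1.85 (SE 0.254, limma adjusted p 0.0133, range 0.000147 to 0.128). Cldn11, the tight junction protein of myelin, fell by 1.34 (SE 0.300, limma adjusted p 0.0497). Trf, the iron carrier made by oligodendrocytes, fell by 1.65 (SE 0.365, limma adjusted p 0.0484), but after quantile normalization its change was -1.32 with an adjusted p of 0.0584, which ran from 0.0017 to 0.203 over the alternatives. The myelin list of 13 genes had a median of -0.99 (camera adjusted p 1.82e-08, and adjusted p = 0.403 with an estimated correlation). In it 2 members were called over all genes and 10 adjusted over the list alone, and its medians in the wild-type arrays were -0.42, 0.45 and 0.03 against -0.82, -1.35 and -0.91 in ob/ob. Sox9, a transcription factor of astrocytes, fell by 1.53 (SE 0.203), from 10.67 (SD 0.122) to 9.13 (SD 0.204), with a limma adjusted p of 0.0118. Aqp4, the water channel of astrocyte endfeet, fell by 0.91 (SE 0.199, limma adjusted p 0.0467). Gfap, the intermediate filament of astrocytes, fell by 1.40 (SE 0.278), from 12.03 (SD 0.0862) to 10.63 (SD 0.244), with a limma adjusted p of 0.0394. After quantile normalization its change was -1.135 with an adjusted p of 0.109, which ran from 0.000927 to 0.2 over the alternatives. The astrocyte list fell with a median of -0.68 (camera adjusted p 1.41e-06, and adjusted p = 0.394 with an estimated correlation), with 3 of 13 members called over all genes and 7 adjusted over the list alone. Of the reactive astrocyte list, Gfap was the 1 member called over all genes (3 adjusted over the list alone), and Vim was lower by 1.07 (SE 0.255, limma adjusted p 0.0592) and did not pass.

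**Figure D1:**
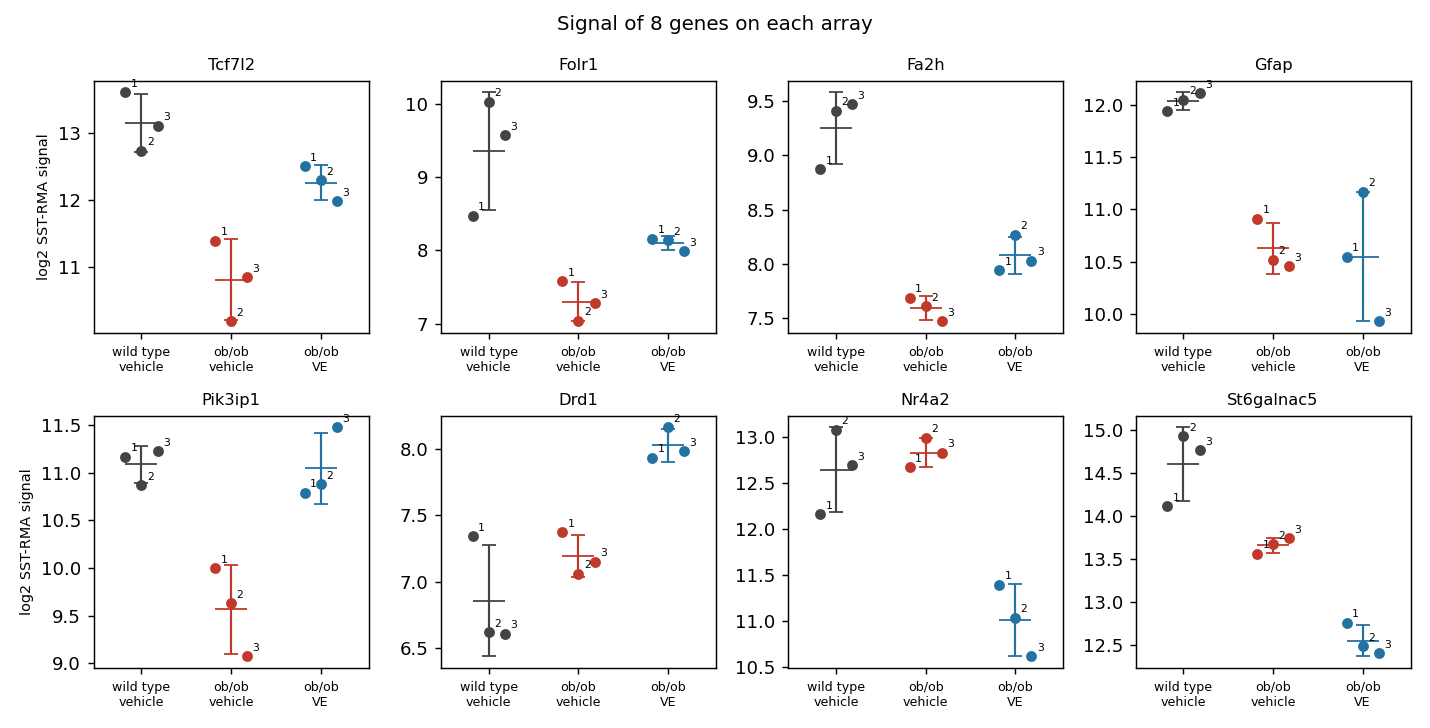
Log2 signal of 8 named genes on each array, with the mean and SD of each group (n = 3).

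Called genes of microglia, and the gene of a ligand that acts on them, were lower in ob/ob brain. Olfml3, a secreted protein of microglia, fell by 1.26 (SE 0.206, limma adjusted p 0.0257, n = 3), C1qb, a complement subunit, by 0.94 (SE 0.191, limma adjusted p 0.0401), and Csf1, the ligand that keeps microglia alive, by 1.13 (SE 0.194, limma adjusted p 0.0285). The list of homeostatic microglia (18 genes) had a median of -0.60 (camera adjusted p 5.63e-07, and adjusted p = 0.374 with an estimated correlation), with 2 members called over all genes and 9 adjusted over the list alone. Among thalamic genes Tcf7l2 went from 13.14 (SD 0.437) to 10.81 (SD 0.601), with a range of adjusted p of 0.000147 to 0.118 over the alternatives. Rgs16, a regulator of G protein signalling, fell by 1.05 (SE 0.230, limma adjusted p 0.0467). The thalamus list of 8 genes had a median of -0.53 (camera adjusted p 0.00622, and adjusted p = 0.374 with an estimated correlation), with 2 members called over all genes and 4 adjusted over the list alone. Single calls stood in other neuronal lists: Car8, of Purkinje cells, fell by 1.09 (SE 0.234, limma adjusted p 0.0463), Nlgn3, a synaptic adhesion protein, by 0.99 (SE 0.205, limma adjusted p 0.0415), and Nptx1, a synaptic pentraxin, by 1.12 (SE 0.234, limma adjusted p 0.0426). Pvalb at -0.90, Gad1 at -0.84 and Rbfox3 at -0.77, markers of interneurons and of neurons at large, did not pass (limma adjusted p 0.0693, 0.0761 and 0.0811).

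Called genes of the fatty acid synthesis, oxidative phosphorylation and ribosomal protein lists were lower in ob/ob brain. Scd1, which makes monounsaturated fatty acids, fell by 1.31 (SE 0.231, limma adjusted p 0.0326, n = 3), and Elovl6, which lengthens fatty acids, by 1.06 (SE 0.217, limma adjusted p 0.0415). The fatty acid synthesis list of 12 genes had a median of -0.81 (camera adjusted p 2.2e-05, and adjusted p = 0.394 with an estimated correlation), with 2 members called over all genes and 7 adjusted over the list alone. The mitochondrial gene Ndufs7, of complex I, fell by 1.40 (SE 0.304, limma adjusted p 0.0463). The oxidative phosphorylation list of 63 genes had a median of -0.49 (camera adjusted p 2.93e-12, and adjusted p = 0.408 with an estimated correlation). Rps13, of the small ribosomal subunit, fell by 1.01 (SE 0.203, limma adjusted p 0.0401). The ribosomal protein list of 53 genes had a median of -0.58 (camera adjusted p 2.31e-09, and adjusted p = 0.452 with an estimated correlation). With all probe sets in 3 equal bins of level, the brightest bin had a median of -0.27, and -0.04 after quantile normalization. The 3 lists of this paragraph are not set against probe sets of like level here, so their falls cannot be told from such a trend. Outside these lists, Calr, the calcium-binding chaperone of the endoplasmic reticulum, fell by 1.74 (SE 0.371, limma adjusted p 0.0455, range 0.000686 to 0.203). Pdia6, a disulfide isomerase, fell by 1.29 (SE 0.279, limma adjusted p 0.0463). Cat, the catalase gene, fell by 1.32 (SE 0.204, limma adjusted p 0.0207), and Bhlhe40, a repressor tied to the circadian clock, by 1.14 (SE 0.222, limma adjusted p 0.0375), while the circadian clock list did not pass (camera adjusted p 0.0854).

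Among the 12 largest named rises in ob/ob brain were genes of the olfactory, vomeronasal and keratin-associated families and predicted genes. Olfr638, an olfactory receptor, rose by 1.40 (SE 0.213), from 8.12 (SD 0.0436) to 9.52 (SD 0.127), with a limma adjusted p of 0.0207 (range 0.000275 to 0.147, n = 3). Vmn1r197, a vomeronasal receptor, rose by 1.23 (SE 0.234, limma adjusted p 0.0366, range 0.00115 to 0.196). Krtap1-4, a hair keratin-associated protein, rose by 1.23 (SE 0.259, limma adjusted p 0.0437, range 0.0017 to 0.205). Scgb2b3, a secretoglobin, rose by 1.56 (SE 0.229, limma adjusted p 0.0193, range 0.000461 to 0.12). Flg2, an epidermal filaggrin gene, rose by 1.29 (SE 0.207, limma adjusted p 0.025, range 0.000606 to 0.169). The zinc finger gene Zfp600 rose by 1.27 (SE 0.220, limma adjusted p 0.0308, range 0.00115 to 0.148). The testis gene Tex38 rose by 1.31 (SE 0.286, limma adjusted p 0.0463, range 0.00232 to 0.213). The predicted genes 1700093K21Rik at 1.64 (SE 0.315), Gm5936 at 1.48 (SE 0.301), Gm20738 at 1.43 (SE 0.280) and Gm2030 at 1.41 (SE 0.282), with Olfr1307 at 1.28 (SE 0.254), completed the 12 largest rises (limma adjusted p 0.0366 to 0.0409). The olfactory receptor list of 1091 probe sets rose with a median of 0.36 (camera adjusted p 4.03e-16, and adjusted p = 0.113 with an estimated correlation), with 20 members called over all genes and 43 adjusted over the list alone. The vomeronasal list of 319 had a median of 0.30 (camera adjusted p 8.3e-09, and adjusted p = 0.113 with an estimated correlation), with 1 call over all genes and 0 adjusted over the list alone. The keratin-associated list of 50 had a median of 0.47 (camera adjusted p 8.3e-09, and adjusted p = 0.374 with an estimated correlation), with 2 calls over all genes and 17 adjusted over the list alone.

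**Figure D2:**
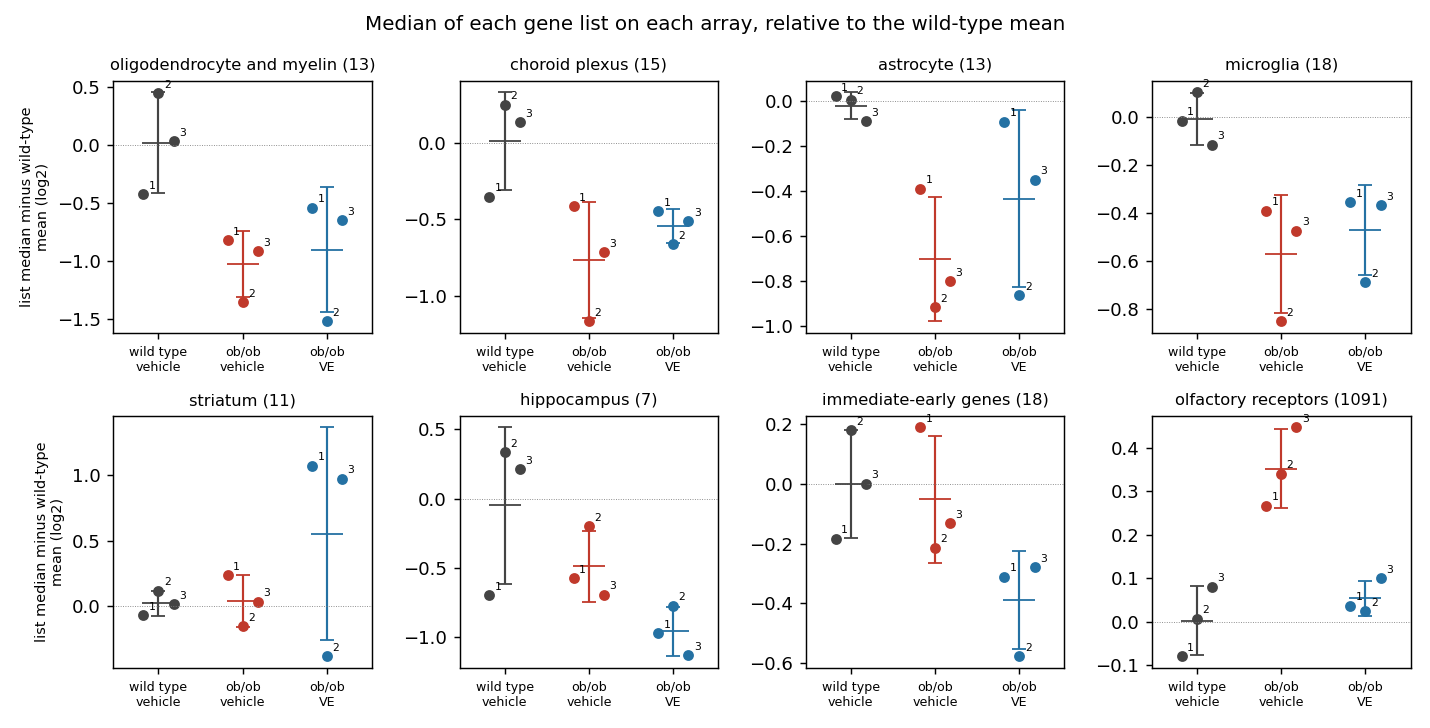
Median of 8 gene lists on each array, relative to the wild-type mean, with the mean and SD of each group (n = 3) and the replicate number beside each point.

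Key genes of leptin signalling and energy balance did not pass in ob/ob brain against wild type. Lepr, the leptin receptor, was at -0.07 (SE 0.185, limma adjusted p 0.858, n = 3), Npy, an appetite peptide, at -0.47 (SE 0.324, limma adjusted p 0.431), and Pomc, a precursor of melanocortins, at 0.56 (SE 0.350, limma adjusted p 0.388). Cartpt, an anorexigenic peptide, was at -0.05 (SE 0.192, limma adjusted p 0.912), Socs3, an inhibitor of leptin receptor signalling, at 0.09 (SE 0.193, limma adjusted p 0.814), and Bdnf, a neurotrophin, at -0.43 (SE 0.314, limma adjusted p 0.466). Lep itself was at 0.07 (SE 0.203, limma adjusted p 0.876), with 4.74 to 5.17 on the 9 arrays. The ob allele is a point mutation that leaves a transcript, so Lep signal checks no label here. In wild type Socs3 stood at 4.40, Pomc at 5.42 and Lepr at 6.83, below the median level of 7.13 over probe sets. Cartpt stood at 7.24, Bdnf at 10.25 and Npy at 11.09. In simulated data 0% of changes of 0.5 log2 units were recovered, so these values do not show that the genes were unchanged. Fkbp5, a target of the glucocorticoid receptor, was at 0.56 (SE 0.258, limma adjusted p 0.247), with a change of 0.85 and an adjusted p of 0.0199 after quantile normalization and a range of 0.00613 to 0.475 over the alternatives. Pmch, the gene of melanin-concentrating hormone, was lower by 3.00 (SE 0.797) with an SD of 2.40 in wild type. Hcrt, of orexin neurons, was at -1.40 (SE 0.460), and Mc3r, a melanocortin receptor, at 1.02 (SE 0.234), and of Pmch, Hcrt and Mc3r none passed (limma adjusted p 0.0752, 0.127 and 0.0544). The leptin and energy balance list had a median of -0.13 (camera adjusted p 0.66), with 1 member higher when adjusted over the list alone. The hypothalamic neuropeptide list had a median of 0.12 but a mean of -0.22 (camera adjusted p 0.834), with 2 members lower when adjusted over the list alone. Over the alternatives the change of Bdnf ran from -0.64 to -0.20, of Npy from -0.59 to -0.21, of Lepr from -0.19 to -0.03, of Pomc from 0.38 to 0.76, and those of Lep, Socs3 and Cartpt took both signs. Agrp, Nnt, Xist and Ddx3y were not named in the annotation used here.

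Over all genes, 281 of 22206 probe sets were called in ob/ob against wild type (limma adjusted p under 0.05), 119 higher and 162 lower, of which 222 had a gene name. At unadjusted p under 0.05 the count was 4457 (2193 higher, 2264 lower), against 1110 by chance, and the smallest adjusted p was 0.0118. The split of calls depended on the scaling between arrays: 42.3% were higher with the deposited values, 60.4% of 631 (381 higher, 250 lower) after quantile normalization, 27% of 614 (166 higher, 448 lower) after centring each array on its median, 60% of 808 (485 higher, 323 lower) after cyclic loess, and 53.1% of 1970 (1047 higher, 923 lower) after quantile normalization without VE array 2. With probe sets in 3 equal bins of level, the dimmest bin had a median of 0.17 and the brightest -0.27, against 0.01 and -0.04 after quantile normalization. The brightest bin held 60 higher and 114 lower calls with the deposited values, and 272 higher and 101 lower calls after quantile normalization. Leaving out VE array 2 gave 2975 calls and leaving out VE array 1 gave 389. Leaving out VE array 3 gave 98, ob/ob array 1 21 and wild-type array 1 20, and the call count was 0 by limma without ob/ob array 2, ob/ob array 3, wild-type array 2 or wild-type array 3 (3079, 2872, 3357 and 3479 at unadjusted p under 0.05). With array weights over the 9 arrays the count was 3601. Those 4 arrays therefore ended each gene call of this comparison, and the adjusted p of Tcf7l2 was 0.112, 0.118, 0.0858 and 0.111 without them. The change of Tcf7l2 stayed between -2.62 and -2.02 over the alternatives.

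Of 56 gene lists, 26 passed in ob/ob against wild type by camera with a preset correlation (3 higher, 23 lower), 7 by fry, and 0 with an estimated correlation (6 at unadjusted p under 0.05). The lists that fell, beside those given above, were antioxidant (median -0.43, camera adjusted p 9.33e-05), amyloid and tau (-0.53, 0.000211), general neuronal (-0.59, 0.000252), cholesterol synthesis (-0.42, 0.00103), glycolysis (-0.40, 0.00622), inhibitory neurons (-0.38, 0.00657), postsynaptic scaffold (-0.41, 0.00666), hippocampus (-0.49, 0.00931) and excitatory neurons (-0.65, 0.00941). The same held for endoplasmic reticulum stress (-0.25, 0.0104), endothelium (-0.34, 0.0105), oligodendrocyte precursors (-0.44, 0.0105), insulin signalling (-0.37, 0.0131), fatty acid oxidation (-0.26, 0.0358) and activated microglia (-0.50, 0.039), each with 3 arrays per group. For these 15 lists adjusted p = 0.394 to 0.568 with an estimated correlation. After quantile normalization the camera adjusted p was 0.321 for glycolysis_glucose_transport, 0.375 for postsynaptic_scaffold, 0.156 for er_stress and 0.0797 for insulin_signalling. The endothelial_barrier call ended without ob/ob array 2 (0.0654), the hippocampus call without ob/ob array 1 (0.0545) or wild-type array 2 (0.0708), and the insulin_signalling call without ob/ob array 3 (0.0621) or wild-type array 1 (0.0529). The fatty_acid_oxidation call ended without wild-type array 3 (0.059) or VE array 2 (0.0526), and the microglia_activated call without ob/ob array 1 (0.0542), ob/ob array 2 (0.0744), wild-type array 2 (0.0803) or VE array 3 (0.0544).

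The remaining 30 lists did not pass in ob/ob against wild type, and beside the leptin and neuropeptide lists their medians with camera adjusted p (3 arrays per group) were as follows. Tissue and region lists were pituitary 0.33 (0.0534), monoamine neurons 0.30 (0.0534), cortex -0.45 (0.132), hypothalamus 0.20 (0.147), hindbrain Hox genes 0.11 (0.514), striatum -0.02 (0.715), cerebellum -0.07 (0.8), olfactory bulb 0.01 (0.941) and ependyma 0.04 (0.952). Cell lists were leukocytes 0.11 (0.168), meningeal fibroblasts -0.14 (0.187), pericytes -0.09 (0.715), adipocytes 0.07 (0.93) and reactive astrocytes 0.03 with a mean of -0.23 (0.205). Receptor lists were GABA receptors -0.42 (0.0611) and glutamate receptors -0.04 (0.514). Immune lists were interferon response -0.05 (0.683), cytokines and NF-kB 0.04 (0.746) and antigen presentation 0.13 (0.767). State lists were circadian clock -0.27 (0.0854), autophagy -0.34 (0.0882), heat shock -0.32 (0.132), neurotrophic plasticity -0.17 (0.188), apoptosis -0.10 (0.338), cell cycle 0.10 (0.514), glucocorticoid response -0.03 (0.749), immediate early genes -0.05 (0.856) and neurogenesis 0.08 (0.856). When adjusted over the list alone, members were called lower in the interferon response (2), circadian clock (2), meningeal (2, with 1 higher), antigen presentation (1), cerebellum (1) and neurotrophic plasticity (1) lists. The lists for erythroid cells and the mitochondrial genome had too few measured members for a test by camera (2 and 0).

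After VE, 2 named genes rose and 43 named genes fell against ob/ob vehicle. Pik3ip1 went from 9.57 (SD 0.468) in ob/ob vehicle to 11.05 (SD 0.375) after VE, beside 11.09 (SD 0.193) in wild type (limma adjusted p 0.0366, range 6.68e-05 to 0.212, n = 3). It was the only gene called lower in ob/ob against wild type (-1.52, SE 0.268, limma adjusted p 0.0326) and higher after VE. Pcdh10, a protocadherin of neurons, rose by 1.45 (SE 0.272), from 9.52 (SD 0.052) to 10.97 (SD 0.426), with a limma adjusted p of 0.0403 (range 0.000157 to 0.215). Nr4a2, an activity-induced nuclear receptor, fell from 12.83 (SD 0.16) to 11.01 (SD 0.39), with a limma adjusted p of 0.0334 (range 5.24e-05 to 0.209). Other immediate early genes had lower values without passing: Nr4a3 at -1.45 (SE 0.320), Arc at -0.97 (SE 0.231) and Fosb at -1.06 (SE 0.260), with limma adjusted p of 0.0649, 0.0836 and 0.0891. The immediate early list of 18 genes fell with a median of -0.33 (camera adjusted p 0.00645, and adjusted p = 0.79 with an estimated correlation), with 1 member called over all genes and 4 adjusted over the list alone. For immediate_early_genes the adjusted p was 0.105 without ob/ob array 1 and 0.102 without VE array 1.

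The 4 striatal genes with the smallest p had higher values after VE without passing. Drd1, the dopamine receptor of direct-pathway neurons, went from 7.19 (SD 0.16) to 8.02 (SD 0.121), n = 3. Rgs9, a striatal regulator of G protein signalling, was at 1.73 (SE 0.481), Tac1, the substance P precursor, at 1.18 (SE 0.371), and Penk, the enkephalin precursor, at 1.69 (SE 0.651), and of Drd1, Rgs9, Tac1 and Penk none passed (limma adjusted p 0.124, 0.124, 0.176 and 0.272). The striatum list of 11 genes rose with a median of 0.66 (camera adjusted p 0.00176, and adjusted p = 0.79 with an estimated correlation), with 0 members called over all genes and 3 adjusted over the list alone. Its medians in the 3 VE arrays, taken from the wild-type mean, were 1.07, -0.39 and 0.97, where VE array 2 was the lower value. Without VE array 2 its median was 1.06 and 6 of its 11 members were called higher. The adjusted p of striatum was 0.102 without VE array 1 and 0.0675 without VE array 3. The striatal sodium channel subunit gene Scn4b was at 1.11 (SE 0.224, limma adjusted p 0.0504, range 0.00179 to 0.209) and did not pass in the fit of a mean per group alone to the deposited values. It passed in 10 of 21 alternatives, among them quantile normalization (1.23, limma adjusted p 0.0139), leaving out VE array 2 (1.18, 0.0181) and the replicate number as a block (0.047).

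Of the genes named next, none passed after VE in the fit of a mean per group alone to the deposited values. With the replicate number as a block, Tcf7l2 (limma adjusted p 0.0334), Cbln2 (0.0361), Slc25a18 (0.0473) and Ptch1 (0.0477) passed. With that block Glt8d2, Rorb, Extl2, Unc13c and Tspan17 did not (limma adjusted p 0.0529 to 0.0838). Tcf7l2 was at 1.45 (SE 0.308), 12.26 (SD 0.262) after VE, with a limma adjusted p of 0.0592 that was 0.03 after quantile normalization (change 1.545) and 0.0335 without VE array 2 (change 1.43) (range 0.00191 to 0.243). Slc25a18, an astrocytic glutamate carrier, was at 0.99 (SE 0.204), Glt8d2, a glycosyltransferase, at 0.98 (SE 0.203), Extl2, of heparan sulfate synthesis, at 0.88 (SE 0.192), and Ptch1, the hedgehog receptor, at 1.06 (SE 0.232), and these did not pass (limma adjusted p 0.054, 0.054, 0.0638 and 0.0649). Cbln2, a synaptic organizer, at 1.60 (SE 0.343), Rorb, a nuclear receptor of cortical layer 4, at 1.23 (SE 0.265), Tspan17 at 0.92 (SE 0.206) and Unc13c, a presynaptic priming factor, at 1.15 (SE 0.260) did not pass (limma adjusted p 0.0598 to 0.0685). Slc25a18, Glt8d2, Extl2, Ptch1, Cbln2, Rorb and Unc13c passed after quantile normalization (changes 0.94 to 1.77, limma adjusted p 0.0102 to 0.0221) and without VE array 2 (0.987 to 1.68, limma adjusted p 0.00441 to 0.0331), with a range over the alternatives of 6.45e-05 to 0.288. Tspan17 did not pass in either (0.0538 and 0.0507). Olfml3 was at 0.80 (SE 0.206, limma adjusted p 0.1), Cldn5, of the blood-brain barrier, at 0.77 (SE 0.202, limma adjusted p 0.104), Folr1 at 0.80 (SE 0.324, limma adjusted p 0.303) and Stard4, a sterol carrier, at 1.02 (SE 0.230, limma adjusted p 0.0685). Homeostatic microglia (median 0.27, camera adjusted p 0.0164), endothelium (0.14, 0.0447), choroid plexus (0.23, 0.0447), oxidative phosphorylation (0.05, 0.0447) and cholesterol synthesis (0.10, 0.0447) passed as lists, and adjusted p = 0.79 to 0.944 with an estimated correlation. Gfap was at -0.08 (SE 0.278, limma adjusted p 0.933), and the myelin list had a median of 0.17 (camera adjusted p 0.238) and the astrocyte list of 0.30 (0.131).

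Leaving out arrays ended those 5 list calls after VE. The adjusted p of microglia_homeostatic was 0.0815 without ob/ob array 2, 0.107 without VE array 1 and 0.0597 without VE array 3, and that of choroid_plexus was 0.385, 0.104 and 0.0765 without the same arrays and 0.0656 without VE array 2. For endothelial_barrier it was 0.298 without ob/ob array 2 (median -0.04), 0.235 without VE array 1 and 0.0765 without VE array 3. For oxidative_phosphorylation it was 0.567 without ob/ob array 2 (median -0.05), 0.0572 without ob/ob array 3, 0.758 without VE array 1 (median -0.14) and 0.263 without VE array 3 (median -0.02). For cholesterol_synthesis it was 0.0911 without ob/ob array 2, 0.0674 without ob/ob array 3, 0.43 without VE array 1 (median -0.03) and 0.0985 without VE array 3.

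Called genes of the olfactory, vomeronasal and keratin-associated families were lower after VE. Olfr638 fell by 1.60 (SE 0.213), to 7.92 (SD 0.351), with a limma adjusted p of 0.0334 (range 6.45e-05 to 0.209, n = 3). Olfr635 fell by 2.36 (SE 0.454, SD 1.24 after VE, limma adjusted p 0.0403), Olfr1338 by 1.75 (SE 0.296), Vmn1r121 by 1.72 (SE 0.281), both with a limma adjusted p of 0.0334, and Vmn1r250 by 1.61 (SE 0.309, limma adjusted p 0.0403). For each of these receptors VE array 2 had the lowest VE value. Without it Olfr635 was at -1.69, Olfr1338 at -1.35, Vmn1r121 at -1.395 and Vmn1r250 at -1.26 (limma adjusted p 0.0102 to 0.0207). Over the alternatives their highest limma adjusted p was 0.209 to 0.231. Krtap19-1 fell by 1.13 (SE 0.217, limma adjusted p 0.0403), and Csprs, of the multicopy Sp100 family, by 1.58 (SE 0.235, limma adjusted p 0.0334). Btbd35f25, of a multicopy family, fell by 1.56 (SE 0.281, limma adjusted p 0.0366). The predicted genes Gm5936 at -1.76 (SE 0.301), Gm20816 at -1.50 (SE 0.258), Gm2030 at -1.44 (SE 0.282) and 4930558K02Rik at -1.42 (SE 0.235) fell too (limma adjusted p 0.0334 to 0.0444). The olfactory receptor list fell with a median of -0.29 (camera adjusted p 1.2e-07, and adjusted p = 0.771 with an estimated correlation), with 14 members called over all genes and 78 adjusted over the list alone. The keratin-associated list fell with a median of -0.39 (camera adjusted p 1.08e-06, and adjusted p = 0.771 with an estimated correlation), with 1 call over all genes and 9 adjusted over the list alone. The vomeronasal list fell with a median of -0.25 (camera adjusted p 0.00645, and adjusted p = 0.771 with an estimated correlation), with 2 calls over all genes and 6 adjusted over the list alone. For vomeronasal_receptors the adjusted p was 0.4 without VE array 1 and 0.0512 without VE array 3.

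Energy balance genes did not pass after VE. Mc3r was at -1.11 (SE 0.234, limma adjusted p 0.0587, n = 3), Lepr at 0.26 (SE 0.185, limma adjusted p 0.588), Npy at -0.01 (SE 0.324, limma adjusted p 0.994), Pomc at -0.20 (SE 0.350, limma adjusted p 0.861) and Cartpt at -0.29 (SE 0.192, limma adjusted p 0.553). Bdnf was at -0.18 (SE 0.314, limma adjusted p 0.859), Fkbp5 at -0.48 (SE 0.258, limma adjusted p 0.453), Socs3 at 0.03 (SE 0.193, limma adjusted p 0.97), Lep at 0.01 (SE 0.203, limma adjusted p 0.993) and Ttr at 0.23 (SE 0.985, limma adjusted p 0.946). After VE, Socs3 (4.52), Lep (4.98), Pomc (5.78) and Lepr (7.02) stood below the median level of 7.13 over probe sets. Without VE array 2 Ttr was at 1.415, Npy at 0.45, Pomc at -0.59, Fkbp5 at -0.18 and Bdnf at 0.17, and Ttr was at 1.23 after quantile normalization (-0.995 to 1.43 over the alternatives). The leptin and energy balance list had a median of -0.16 (camera adjusted p 0.464, 1 member lower when adjusted over the list alone) and the hypothalamic neuropeptide list of -0.04 (0.79).

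Over all genes, 108 probe sets were called after VE against ob/ob vehicle (limma adjusted p under 0.05), 3 higher and 105 lower, and 45 of them had a gene name. At unadjusted p under 0.05 the count was 2962 (712 higher, 2250 lower), against 1110 by chance. The 108 probe sets held 93 distinct sets of values, and with 1 probe set per distinct set of values the count was 85 (3 higher, 82 lower). With only the probe sets that carry 1 gene symbol the count was 0 (2381 at unadjusted p under 0.05), and with only the 6 arrays compared it was 0 (2281 at unadjusted p under 0.05). The share of higher calls was 2.78% with the deposited values, 18.5% of 324 (60 higher, 264 lower) after quantile normalization, 17.3% of 376 (65 higher, 311 lower) after cyclic loess, 26.6% of 297 (79 higher, 218 lower) after scaling to equal SD, and 28% of 418 (117 higher, 301 lower) after quantile normalization without VE array 2. Leaving out VE array 2 gave 403 calls (122 higher, 281 lower), VE array 1 134 and VE array 3 96. Leaving out wild-type array 1 gave 16, and the count was 0 by limma without ob/ob array 1, 2 or 3 or wild-type array 2 or 3 (2848, 2212, 1999, 2642 and 2621 at unadjusted p under 0.05). These 5 arrays each ended the gene calls after VE (limma adjusted p of Nr4a2 0.0656 to 0.209 without them), while the change of Nr4a2 stayed between -2.16 and -1.62 over the alternatives. Of 56 lists, 10 passed by camera (6 higher, 4 lower), and 0 passed by fry (8 at unadjusted p under 0.05) or with an estimated correlation (3 at unadjusted p under 0.05). The other 46 lists had camera adjusted p from 0.0557 to 0.994, with at most 2 members of a list called when adjusted over the list alone.

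The 5 largest called falls among named genes in VE brain against wild type were in Ndst4, St6galnac5, Shisa6, Nr4a3 and Nr4a2. St6galnac5, a ganglioside sialyltransferase, went from 14.60 (SD 0.429) to 12.55 (SD 0.183), n = 3. Ndst4, of heparan sulfate synthesis, fell by 2.25 (SE 0.333, limma adjusted p 0.0429), and Shisa6, an AMPA receptor partner, by 2.01 (SE 0.291, limma adjusted p 0.0429). Nr4a3 fell by 1.95 (SE 0.320), from 14.23 (SD 0.758) to 12.28 (SD 0.111), and Nr4a2 by 1.63 (SE 0.267), both with a limma adjusted p of 0.0472. After quantile normalization Ndst4 was at -2.09, St6galnac5 at -1.56, Shisa6 at -1.66, Nr4a3 at -1.50 and Nr4a2 at -1.28, with limma adjusted p of 0.166 to 0.227. With the replicate number as a block, the limma adjusted p was 0.03 for St6galnac5, 0.0643 for Shisa6, and 0.0711 for Ndst4, Nr4a3 and Nr4a2. Over the alternatives it ran from 1.6e-06 to 0.244 for St6galnac5, 6.49e-06 to 0.278 for Ndst4, 1.79e-05 to 0.278 for Shisa6, 2.82e-05 to 0.315 for Nr4a3 and 1.06e-05 to 0.314 for Nr4a2. Prox1, of dentate granule cells, was at -1.70 (SE 0.313), Neurod2, of cortical and hippocampal neurons, at -1.24 (SE 0.261), Gfap at -1.48 (SE 0.278), Serpina3n, a protease inhibitor of reactive astrocytes, at -1.27 (SE 0.236) and Sox9 at -1.04 (SE 0.203), and these did not pass (limma adjusted p 0.0634, 0.0883, 0.0634, 0.0634 and 0.075). Gfap passed in 4 of 21 alternatives, among them leaving out VE array 2 (-1.79, limma adjusted p 0.00494), with a range of 3.2e-06 to 0.369. C1qb at -0.91 (SE 0.191) and Elovl5, a fatty acid elongase, at -0.91 (SE 0.187) did not pass either (limma adjusted p 0.0883 and 0.0882). No gene was called higher, and the 5 higher genes with the smallest unadjusted p above the median level, none of which passed, were Drd1 at 1.17 (SE 0.230, limma adjusted p 0.0779), Jrkl at 0.76 (SE 0.190, 0.149), Unc13c at 1.01 (SE 0.260, 0.156), Cts3 at 0.97 (SE 0.254, 0.161) and Cpne5 at 0.85 (SE 0.224, 0.165).

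Gene lists of VE against wild type fell in 19 cases and rose in 3, of 56, by camera with 3 arrays per group. The ribosomal (median -0.63, camera adjusted p 1.03e-09), oxidative phosphorylation (-0.50, 4.93e-09), myelin (-0.97, 1.78e-07) and hippocampus (-0.83, 2.09e-05) lists fell, and the striatum list rose (0.57, 5.48e-05). In these 5 lists adjusted p = 0.532 to 0.577 with an estimated correlation, and 9 myelin, 5 hippocampus and 3 striatum members were called when adjusted over the list alone. Falls also came in astrocytes (-0.51, 0.000196), postsynaptic scaffold (-0.53, 0.00027), general neuronal (-0.57, 0.000628), fatty acid synthesis (-0.69, 0.000721), glycolysis (-0.54, 0.000721), immediate early genes (-0.39, 0.000721), homeostatic microglia (-0.44, 0.000721), choroid plexus (-0.37, 0.00144) and activated microglia (-0.41, 0.00782). Endoplasmic reticulum stress (-0.42, 0.00782), antioxidant (-0.28, 0.00782), amyloid and tau (-0.43, 0.0132), reactive astrocytes (-0.34, 0.0172), thalamus (-0.52, 0.0291) and excitatory neurons (-1.14, 0.0329) fell too. The olfactory (0.05, 0.000386) and vomeronasal (0.07, 0.000721) lists passed as higher, and for these 17 lists adjusted p = 0.532 to 0.591 with an estimated correlation. By fry 1 list passed, reactive astrocytes (adjusted p 0.0305), and with an estimated correlation 0 lists passed (3 at unadjusted p under 0.05). The other 34 lists had camera adjusted p from 0.0647 to 0.914, among them the keratin-associated list with a median of 0.00333 (0.133).

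Scaling and single arrays mattered for the lists of VE against wild type. After quantile normalization the median of the astrocytes list was 0.04 (camera adjusted p 0.35), against -0.51 with the deposited values, and it was 0.06 after quantile normalization without VE array 2. After quantile normalization camera adjusted p was 0.865 for olfactory_receptors, 0.587 for vomeronasal_receptors, 0.35 for postsynaptic_scaffold, 0.664 for neuron_general, 0.664 for glycolysis_glucose_transport, 0.404 for antioxidant_nrf2, 0.194 for er_stress, 0.147 for oxidative_phosphorylation, 0.664 for amyloid_tau, 0.419 for excitatory_neurons and 0.185 for thalamus. The thalamus call ended without wild-type array 1 (0.0966), VE array 1 (0.153) or VE array 3 (0.128), and the excitatory_neurons call without wild-type array 1 (0.212) or VE array 3 (0.0564). The reactive_astrocytes call ended without wild-type array 1 (0.0518) or VE array 1 (0.118), the amyloid_tau call without wild-type array 1 (0.0518) or VE array 2 (0.077), and the antioxidant_nrf2 call without VE array 2 (0.0626). The hippocampus medians of the VE arrays, taken from the wild-type mean, were -0.97, -0.77 and -1.13, while the wild-type arrays stood at -0.70, 0.34 and 0.21.

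Over all genes, 22 probe sets were called in VE against wild type (limma adjusted p under 0.05), 0 higher and 22 lower, and 20 had a gene name. At unadjusted p under 0.05 the count was 2707 (661 higher, 2046 lower), against 1110 by chance. The count was 0 after quantile normalization (2328 at unadjusted p under 0.05), after cyclic loess (2490) and after scaling to equal SD (2286), and 19 (7 higher, 12 lower, 36.8% higher) after quantile normalization without VE array 2. With the replicate number as a block it was 2 (3055 at unadjusted p under 0.05). Leaving out VE array 1 gave 158 calls, VE array 2 73 (8 higher, 65 lower) and wild-type array 1 30. By limma the count was 0 without VE array 3, any of the 3 ob/ob arrays, or wild-type array 2 or 3 (3022, 2472, 2419, 2382, 1818 and 1940 at unadjusted p under 0.05). These 6 arrays each ended the gene calls of this comparison. The change of St6galnac5 was between -2.29 and -1.52 over the alternatives. Over the 3 groups together, the F test of limma called 238 probe sets.

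Of the 281 probe sets called in ob/ob against wild type, 257 had a change of opposite sign after VE (91.5%). Simulated data without a VE effect, in which the shared ob/ob arrays alone link the 2 changes, called 2959 to 3334 probe sets and gave 68.9% of opposite sign among them (67.2 to 70.7 over 100 simulations). Among the 281 of smallest p in each simulation, a measure added after the results were seen, it was 74.9% (68.3 to 81.9), with errors drawn separately for each probe set. Errors shared by the probe sets of an array were not simulated, so these ranges can be too narrow to weigh the 91.5% against. The simulations also took the observed wild-type and ob/ob means as true, so chance differences between them counted as ob/ob effects. That can make the simulated shares of opposite sign too low. The simulated correlation given below has both limits and can be too weak. All 119 called higher in ob/ob and 138 of the 162 called lower had the opposite sign. There were 55 probe sets called both higher in ob/ob and lower after VE, and 1 called lower and then higher, Pik3ip1. Another 11 were called lower than wild type in both ob/ob and VE. These comparisons share arrays, and no value without an effect was computed for the overlaps. Over all probe sets the covariance of the 2 changes was -0.0941, against -0.0402 without a VE effect, and their correlation was -0.58 against -0.26 in simulated data (exact permutation p 0.0762 over 1680 assignments of arrays, 1-sided, n = 9). The exact permutation p was 0.0119 after quantile normalization, 0.0179 without VE array 2, and 0.286 without ob/ob array 2 or without ob/ob array 3. These p values refer to 3 groups that are all alike, so they do not test the lack of a VE effect alone. After VE, Olfr638 was at 7.92 (8.12 in wild type, 9.52 in ob/ob), Vmn1r197 at 7.86 (7.79 and 9.01), Fa2h at 8.08 (9.25 and 7.59) and Cryab at 10.70 (12.21 and 10.36). Separation of the 3 groups over all probe sets had a pseudo-F of 2.02 (exact permutation p 0.00714 over 280 assignments). For pairs of groups the pseudo-F was 3.81, 1.54 and 1.59 for ob/ob against wild type, VE against ob/ob and VE against wild type (exact permutation p 0.1, 0.2 and 0.1, where 0.1 is the lowest value possible with 3 against 3).

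**Figure D3:**
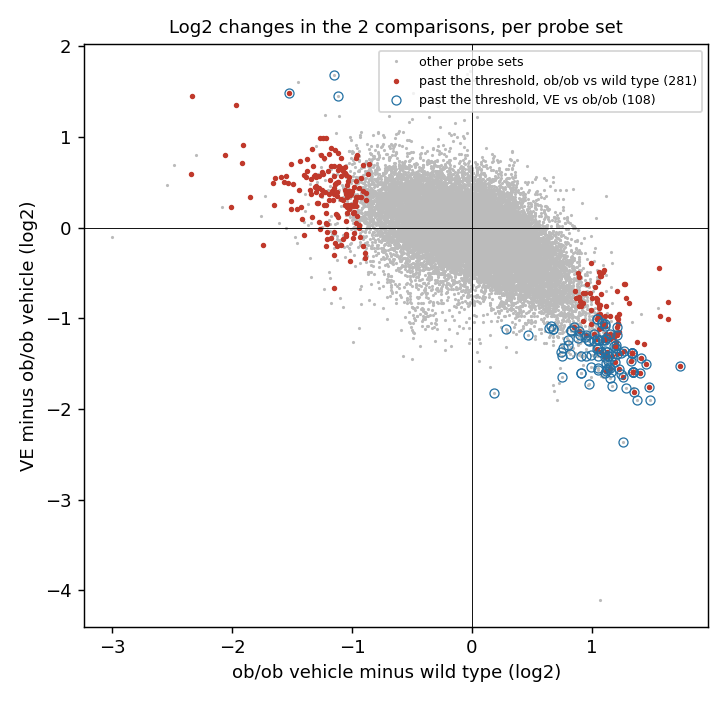
Change in ob/ob against wild type and change after VE against ob/ob for each probe set, with the 281 called in the first comparison in red and the 108 called in the second in blue. The shared ob/ob arrays give the 2 changes a negative correlation even without a VE effect.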

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

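The alternatives of this part were fixed before the data were examined, except cyclic loess, scaling to equal SD, quantile normalization without VE array 2 and 1 probe set per distinct set of values, which were chosen after seeing the results. For ob/ob against wild type (281 calls by limma) the count was 4457 by the authors' rule, 1204 at adjusted p under 0.1, 631 after quantile normalization, 614 after centring, 3601 with array weights, 2626 with the 2 compared groups alone, 808 after cyclic loess, 599 after scaling to equal SD, 1970 after quantile normalization without VE array 2, and 0 to 2975 over the 9 left-out arrays. For VE against ob/ob (108 calls) it was 2962 by the authors' rule, 433 at adjusted p under 0.1, 225 with trend and robust moderation, 180 above the median level, 324 after quantile normalization, 71 after centring, 3307 with array weights, 0 with 1-symbol probe sets, 0 with the 2 compared groups alone, 376 after cyclic loess, 297 after scaling to equal SD, 418 after quantile normalization without VE array 2, and 0 to 403 over left-out arrays. For VE against wild type (22 calls) it was 2707 by the authors' rule, 109 at adjusted p under 0.1, 10 with trend and robust moderation, 49 above the median level, 0 after quantile normalization, 7 after centring, 3286 with array weights, 0 with the 2 compared groups alone, 0 after cyclic loess, 0 after scaling to equal SD, and 0 to 158 over left-out arrays. For any difference among the groups (238 calls) it was 4215 by the authors' rule, 884 at adjusted p under 0.1, 364 with trend and robust moderation, 364 above the median level, 473 after quantile normalization, 368 after centring, 6321 with array weights, 122 with 1-symbol probe sets, 629 after cyclic loess, 440 after scaling to equal SD, 1298 after quantile normalization without VE array 2, and 0 to 1926 over left-out arrays. VE array 2 is not in the comparison of ob/ob against wild type, so leaving it out altered no log2 change there. The rise from 281 to 2975 calls without it came through the estimate of the spread, which the 9 arrays share. Tcf7l2 stayed at -2.33, with a limma adjusted p of 0.00107 in place of 0.0118. The causes of the other moves were not tested.

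With the replicate number as a replicate block, VE against wild type had 2 calls instead of 22, VE against ob/ob had 6 lists instead of 10, and the reversal covariance was -0.0941 (permutation p 0.0333). That permutation p is not exact, because arrays were reassigned across replicate numbers after the replicate means had been removed. The replicate numbers were checked for pairing over 9 pairs of arrays with the same number, by correlations of deviations from the group means. These were -0.0323 to 0.331, with 4 over 0.1, against -0.289 to 0.111 for arrays of unlike numbers. The numbers were not taken as pairs outside the block alternative, but an effect shared by arrays of the same number is not excluded.

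Of the lists of ob/ob against wild type (26 by camera), 16 passed above the median level, 7 by fry and 0 with an estimated correlation. Of those of VE against ob/ob (10), 5 passed above the median level, 0 by fry, 0 with an estimated correlation and 2 to 20 over left-out arrays, with the highest count without VE array 2 and the lowest without VE array 1. Of those of VE against wild type (22), 10 passed after quantile normalization, 11 after cyclic loess, 11 after scaling to equal SD, 11 after quantile normalization without VE array 2, 1 by fry and 0 with an estimated correlation. The reversal covariance (-0.0941, exact permutation p 0.0762) was -0.121 above the median level (exact permutation p 0.0238), -0.098 after quantile normalization (0.0119), -0.0943 after cyclic loess (0.0119), -0.101 after scaling to equal SD (0.0119), -0.0989 after quantile normalization without VE array 2 (0.0179), and -0.137 to -0.0729 over left-out arrays (0.0179 to 0.286). The pseudo-F of group separation (2.02) was 1.58 without ob/ob array 3 (exact permutation p 0.0607) and up to 2.70 over left-out arrays. The causes of these moves were not tested.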

Other observations

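The tests of VE array 2, of the olfactory rise and of the falling lists were chosen after seeing the results; for 7 of these 8 the outcome each explanation called for was written before the test was run, and for the genomic DNA test after it. The SE over arrays and the demand for 2 SE were added after first values of the olfactory and of the choroid plexus, myelin and astrocyte tests had been seen. Splits of the 6 arrays of each comparison, with the third group kept in the fit, gave 281 calls in the real grouping and at most 0 in another for ob/ob against wild type, 108 and 0 for VE against ob/ob, and 22 and 6 for VE against wild type. In each of the 3 comparisons 1 split, the real one, had as many calls, and 10 splits are too few for a share under 0.05. A strain segment around Lep was tested by the genes within 20 Mb among the 100 smallest p with 1 direction in both ob/ob groups. There was 1 such gene against 1.29 expected (odds ratio 0.774, Fisher exact p 1), which argues against the segment as a source of many of those genes. With so few expected, the test could not exclude it as a source of a few.

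VE array 2 stood apart from the other 8 arrays. A narrower spread of its values is 1 explanation: after quantile normalization, which removes it, the mean correlation of VE array 2 with the others was still 0.969 against 0.982 for the lowest other array, which argues against spread as the whole cause. A different brain region or cell make-up is another: 3 of 23 region and cell lists (striatum, thalamus and oligodendrocyte precursors) deviated beyond level-matched random lists, against 1.15 by chance and up to 7 on other arrays, so this stays open. A degraded or otherwise different sample was not tested. The striatum list was high on VE arrays 1 and 3, and without VE array 2 its median after VE was 1.06.

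The olfactory, vomeronasal and keratin-associated lists rose in ob/ob brain by camera with a preset correlation (the vomeronasal list with 1 call over all genes), and the brightest bin of probe sets had a median of -0.27 as deposited but -0.04 after quantile normalization, with 60 higher and 114 lower calls against 272 and 101. For a narrower spread of values on the ob/ob arrays, the olfactory difference of per-array list medians was 0.197 after quantile normalization (SE 0.0446) against 0.349 before. It was above the bound of 0.18 written beforehand by less than its SE, so this explanation stays open. The measure computed first, the median of the members' fitted changes, was 0.204 against 0.357 before. For a trend shared by all dim probe sets, the olfactory median exceeded that of level-matched probe sets by 0.24 (SE 0.0501), which argues against it as the whole cause. For genomic DNA carried over into the RNA, 45 named Y chromosome probe sets had a median of 0.64 (SE 0.125) against 0.349 for olfactory receptors, but that test was chosen after Y-linked genes were seen among the largest rises, so it restates what was seen and this explanation stays open. It was first run on 219 probe sets placed on Y by probe ID (0.824) and then on the 45 that RefSeq places there. Of these, 7 short-arm genes, chosen after their values were seen, stood at -0.0644 (SE 0.0758) and the other 38 at 0.746 (SE 0.138). That split cannot decide on carry-over, because the 7 were chosen by their values and DNA signal depends on copy number. Other causes of a rise in multicopy families stay open too.

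The choroid plexus, myelin and astrocyte lists fell in ob/ob brain. For a trend with signal level, 3 of 3 lists lay below level-matched lists by more than 2 SE, which argues against that trend. For a narrower spread on the ob/ob arrays, the highest of the 3 differences after quantile normalization was -0.405 (SE 0.0768, astrocytes), which argues against spread as the whole cause. For uneven amounts of choroid plexus and other regions between dissected samples, the choroid plexus median ranged by 0.757 over the 3 ob/ob arrays against a group difference of 0.84, so uneven dissection stays open. Dissected regions or cell counts per animal would be needed to tell these apart.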
